A study of Mus musculus with 16 samples.

How the data were processed

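The series holds 16 microarrays of the ascending aorta of double knockout mice, from both sexes, fed chow or a high-fat diet. RNA was hybridised in 1 colour (Cy3). The deposited table gives the intensity of 62976 features on each array, on a linear scale from 3.44 to 583000 and to 3 significant digits. Signals were extracted with Agilent Feature Extraction 10.5, per the submitters' processing notes. The background correction and any scaling by the authors are not given in the sources used here. The 75th percentile of intensity ran from 462 to 809 between arrays, so the deposited intensities had not been brought to a common level. The values of each array ended in a local floor. A value was counted as at the floor when it lay within 1.3 times the 2nd percentile of the features up to 200 places away on either side.

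The features carry numbers from 1 to 62976, and the files used here do not pair these numbers with probes or genes. Results are therefore given by feature number, control spots were not separated from the rest, and spots of 1 probe were not averaged. The 38 gene lists fixed before the data were examined, which included markers of arterial, immune, fat and muscle cells, were not tested. For the same reason neither the covariates for tissue makeup nor the mean over the probes of a gene were run.

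Groups were taken from the titles and sample characteristics. The chow group had 9 arrays and the high-fat group 7, and 7 arrays were labelled female and 9 male. By the labels, each high-fat array had 1 chow array of the same sex and week, which gave 7 pairs, 3 female and 4 male. On 9 features that part the other 14 arrays by sex, the arrays labelled female and male of high fat week 4 each lay with the other sex. Both week 4 pairs may therefore join different sexes, and every measure over the 7 pairs rests on the sex and week labels as given. The descriptions of the female high-fat arrays of weeks 8 and 20 give weeks 4 and 8. The weeks of the titles and characteristics were used. Those of the descriptions were an alternative for the slope on high fat and the difference of slopes alone. The female pairs of weeks 8 and 20 may thus join different weeks, and no measure over the pairs was repeated for this. The labels state neither the number of mice behind an array nor its slide or scan. The p-values thus measure the spread between these arrays, which may be partly technical, and no batch could be tested.

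The design written before the data were examined assumed log2 values. Because the table held linear intensity, each value was taken as log2 and the 75th percentile of its array was subtracted. The dimmest 40% of features by mean over the 16 arrays were left out, which left 37785. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05. The diet effect was fitted on the 14 arrays of weeks 4 to 20 with sex and week as covariates. Diet effects of single weeks came from 1 fit of the diet-by-week cells over all 16 arrays, with sex as covariate. At week 14 each diet had 1 array, which was assumed to vary like the arrays of the other cells. Slopes per week came from 1 fit over all 16 arrays with an intercept and a slope for each diet and sex as covariate. The slopes thus rest on the sex labels, and no alternative for them left sex out. The sex difference, female minus male, had diet and week as covariates, and the interaction of diet and sex had week.

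The rule for named items, written before the data were examined, took the features with the smallest unadjusted p in each direction where too few passed. Because the features have no gene names here, at most 2 in each direction were named for a comparison. The 4 features named for the sex labels were chosen after their values were seen. Measures over the 7 pairs were tested exactly over the 64 distinct exchanges of chow and high fat within pairs, which allow a smallest p of 0.0156. They were repeated without the week 4 pairs, which leaves 5 pairs, 16 exchanges and a smallest p of 0.0625, and with the high-fat arrays of week 4 paired the other way. These 5 exact tests and their repeats, the search for features with 2 separate ranges and the search for features that part the sexes were chosen after the data were seen.

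The fits were tested on simulated data in which 200 of 37785 features were changed. For the diet effect, 45.5% of features changed by 1 on the log2 scale were recovered, 82.5% of those changed by 2 and 95% of those changed by 3. For the sex difference the shares were 36.5%, 85.5% and 94%. For the slope on high fat, total changes of 1, 2 and 3 gave 1%, 50.5% and 77.5%. Each simulation called 0 to 15 unchanged features. The noise was drawn independently for each feature, whereas on the real arrays the first principal component held 33.2% of the variance. In other splits of the real arrays, the diet fit called up to 725 features. The shares and false calls thus hold for independent features alone. The number of arrays limits the precision.

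The alternatives tried were quantile normalization, median centring, other filters on dim features, robust and trend-free variance models, array weights, pairs as a block, other covariates, subsets of the arrays and each array left out in turn. Alternatives chosen after the data were seen were no scaling between arrays, a common floor, the first principal component as a covariate, sex left out as a covariate of the diet effects, and both high-fat arrays of week 4 left out. The general settings were also added to the single weeks after the data were seen. Principal components were computed on the 37785 features. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.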

Results

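Gene expression was measured in the ascending aorta of double knockout mice on chow or a high-fat diet. The knocked-out genes are not named in the labels. Chow arrays covered weeks 0, 4, 8, 14 and 20 and high-fat arrays weeks 4, 8, 14 and 20, with 1 female and 1 male array per diet and week, except week 14, which had 1 male array per diet. The median intensity ran from 41.1 to 75.4 between arrays, and 21.3% to 36.5% of the features of an array lay at its floor. Of the 62976 features, 36000 lay at the floor on 0 arrays and 4508 on all 16. Correlations between arrays, across features on the log2 scale, ran from 0.933 to 0.986.

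Arrays of both diets and both labelled sexes lay at each end of the first principal component. The first principal component held 33.2% of the variance and the second 20.8%. The first component was higher on high fat in 5 of the 7 pairs, with a mean difference of 57.0 ± 137 (SD, n = 7 pairs), and the exact two-sided p was 0.281.

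**Figure D1:**
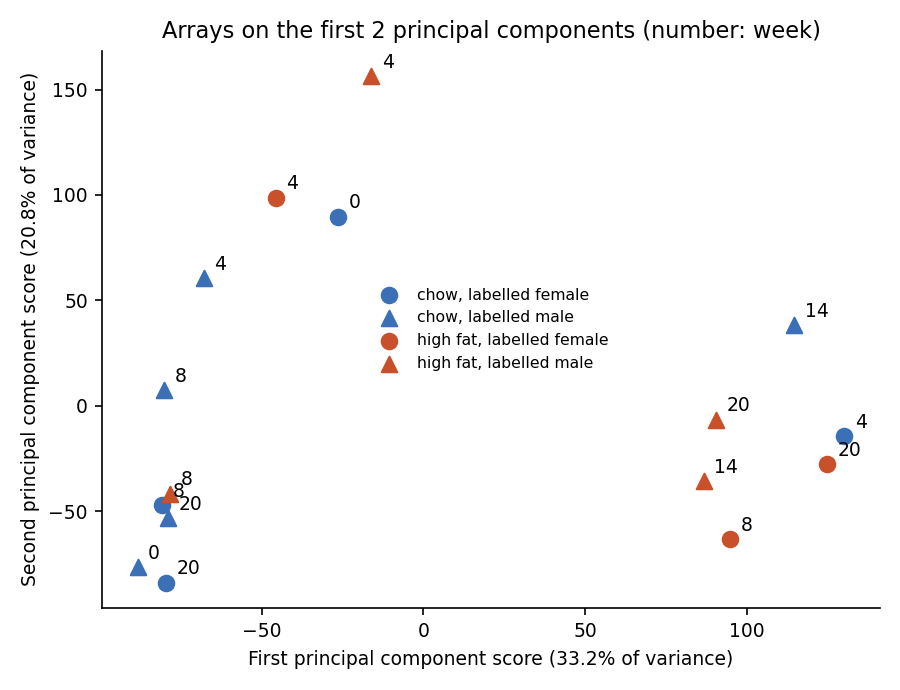
Scores of the 16 arrays on the first (x axis, 33.2% of variance) and second (y axis, 20.8%) principal components, as weighted sums of centred log2 intensity. Colour marks the diet, shape the labelled sex and the number the week; arrays of both diets lie at both ends of the first component.

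Some features had 16 values that fell into 2 separate ranges. There were 728 with a gap of over 4-fold and at least 3 arrays on each side, and 336 of them, or 46.2%, were high on the same 6 arrays. These were the chow female array of week 4, the high-fat female arrays of weeks 8 and 20, the chow and high-fat male arrays of week 14 and the high-fat male array of week 20. The median intensity of the 336 features was 721 to 2805 on these arrays and 5.29 to 10.4 on the other 10. A further 132 features were high on 4 of the 6 arrays, with medians of 349 to 821.5. They were low on the high-fat female arrays of weeks 8 and 20, at 9.44 and 25.1. When the values of each feature were shuffled over the arrays, no more than 3 features shared a partition in any of 100 shuffles. Each feature was shuffled apart from the others, which removes any joint variation, so a low number was largely fixed by the method. Features that vary together, or spots of the same probe, which were not averaged, could exceed it. The shuffles thus cannot tell whether 336 is more than such features would give. The number of features with 2 separate ranges that parted chow from high fat was 0 of 728. This count needs an exact split of all 16 arrays, with the week 0 chow arrays included. It leaves out features that differ by diet on some arrays or by less, so it says little about the diet.

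**Figure D2:**
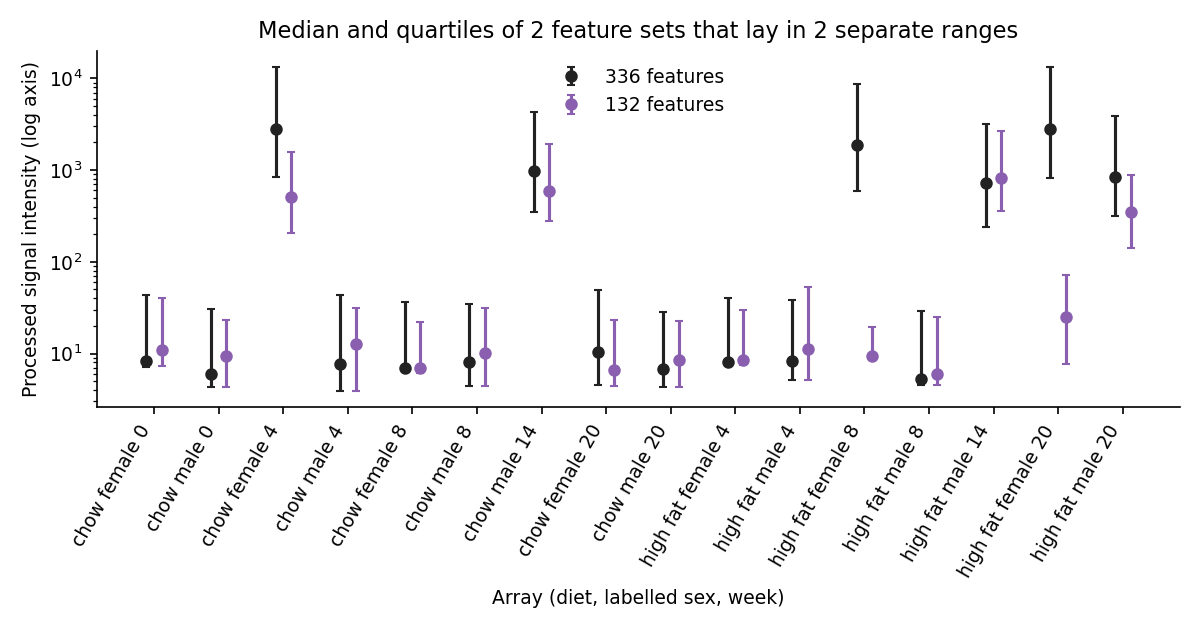
Intensity (y axis, log scale) of the 336 features high on 6 arrays and of the 132 features high on 4 of them, on each of the 16 arrays (x axis). Points are medians over features and bars run from the lower to the upper quartile; the 336 features had medians of 721 to 2805 on 6 arrays and 5.29 to 10.4 on the others.

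The first comparison asked how the high-fat diet changed the aorta over weeks 4 to 20. Feature 20991 was 2.44-fold higher on high fat (log2 difference 1.28 ± 0.148, SE, n = 7 per diet) and higher in 7 of 7 pairs. Its level relative to the 75th percentile was 1.27 ± 0.542 on chow and 2.56 ± 0.418 on high fat (log2, SD), and its adjusted p was 0.135. The chow arrays of week 0, outside this comparison, were at 2.47 (female) and 1.12 (male), the first within the range on high fat of 1.94 to 3.03. Feature 10928 was 3.21-fold higher (log2 difference 1.68 ± 0.246, SE), again in 7 of 7 pairs, with an adjusted p of 0.613. The male chow array of week 0 lay within the range of feature 10928 on high fat, 4.94 to 6.47, and the female one was at 3.75. Feature 61898 was lower on high fat by a log2 difference of -1.07 ± 0.181 (SE), and feature 11589 by -0.69 ± 0.125 (SE), each in 7 of 7 pairs and each with an adjusted p of 0.618. Feature 61898 was at -2.75 on average on high fat and at -3.02 on the female and -1.70 on the male chow array of week 0. With the high-fat arrays of week 4 paired with the other labelled sex, these 4 features still differed in the same direction in 7 of 7 pairs. They were picked for the smallest p on these same arrays, so agreement over the pairs is no further support. With limma, 0 of 37785 features passed the adjusted threshold of 0.05 and 0 passed 0.1. At an unadjusted p under 0.05 there were 2755 features, 899 higher and 1856 lower on high fat, against 1889 by chance. With no scaling between arrays there were 7178, 202 higher and 6976 lower. Over the settings other than single arrays left out the count ran from 1679 to 7178, and with single arrays left out from 1653 to 4250. With median centring or with array weights, feature 20991 passed, as 1 feature in each.

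**Figure D3:**
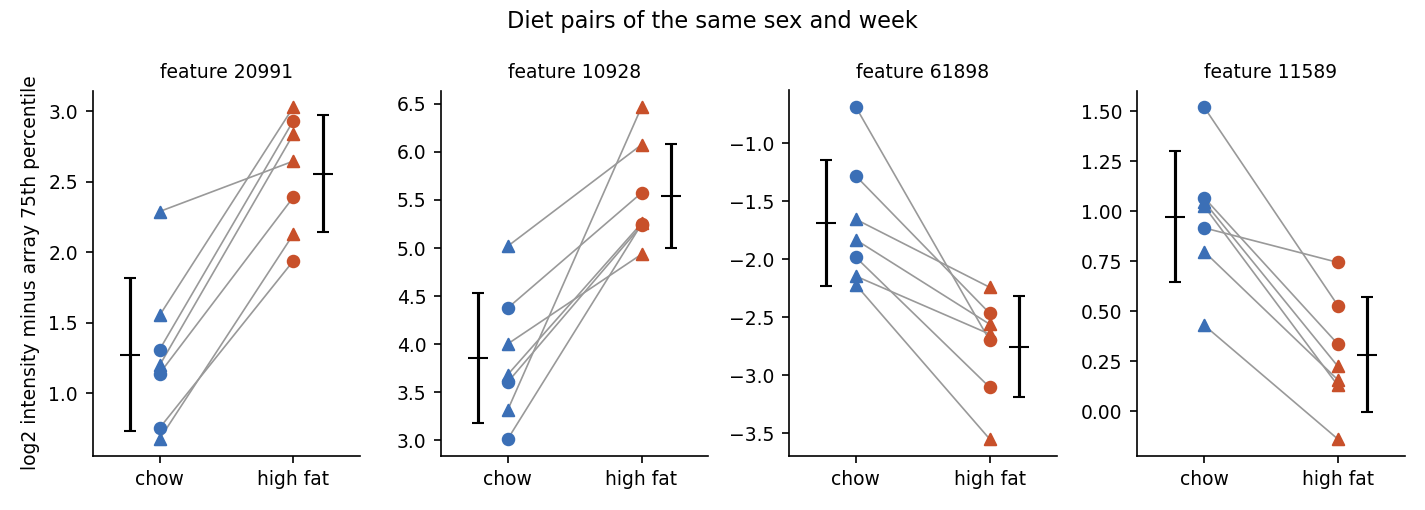
Level of the 4 named diet features (y axis, log2 intensity minus the 75th percentile of the array) on chow and high fat (x axis). Lines join the 7 pairs of the same labelled sex and week, circles are labelled female and triangles male, and black bars give mean ± SD. The features were picked on these same arrays, and each differed in the same direction in 7 of 7 pairs.

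The 7 diet differences were then set against each other over all features. The mean correlation between pairs, across features, was 0.00518, with a range of -0.571 to 0.654, and 8 of 21 correlations were above 0 (exact one-sided p = 0.344). The mean differences of the female and male pairs had a correlation of 0.245 (exact one-sided p = 0.297), with pairs sexed by label. It was 0.351 without the week 4 pairs (exact one-sided p = 0.25, 5 pairs) and 0.203 with the high-fat arrays of week 4 paired the other way (exact one-sided p = 0.359). The mean differences of weeks 4 and 8 against weeks 14 and 20 had a correlation of 0.135 (exact one-sided p = 0.312). Features are not independent replicates. For the female pairs of weeks 8 and 20, the description of the high-fat array gives another week, and no measure was repeated for this. Each female pair thus has a sex or week label in doubt. In 7 of 7 pairs, 187 features were higher and 522 lower on high fat, and 17 of the 64 exchanges within pairs gave a total as large as these 709 (exact p = 0.266). After Benjamini-Hochberg adjustment over these 5 exact tests, including that of the first component, each p was 0.344. Without the week 4 pairs, the mean correlation between pairs was 0.122, that of earlier against later weeks 0.414 and the mean difference on the first component 104.7. In the same direction in 5 of 5 pairs were 3307 features. The 5 exact p then ran from 0.188 to 0.25, where 0.0625 is the smallest possible, and with the other pairing from 0.125 to 0.359.

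By single week, limma called 0 features for diet at weeks 4, 8 and 20, where 1325, 831 and 4407 features had an unadjusted p under 0.05. Week 20 had the smallest adjusted p of these, 0.289. Fits on the 4 arrays of a week alone, with 1 residual degree of freedom, called 0 features at week 4, with 1810 at an unadjusted p under 0.05. They called 88 at week 8, 8 higher and 80 lower on high fat, with a smallest adjusted p of 0.0059 and 1789 at an unadjusted p under 0.05. At week 20 they called 476, 465 higher and 11 lower, with a smallest adjusted p of 0.00241 and 5787 at an unadjusted p under 0.05. The 4407 of the fit over all 16 arrays were 1788 higher and 2619 lower. The descriptions of the female high-fat arrays of weeks 8 and 20 give weeks 4 and 8, and no single-week fit used those weeks. Both high-fat arrays of week 20 were among the 6 arrays on which the 336 features were high, and both chow arrays of week 20 were not. Their scores on the first component were 125 and 90.4 on high fat and -79.5 and -79.0 on chow. With this component as a covariate of the fit over all 16 arrays, the week 20 count at an unadjusted p under 0.05 was 793 in place of 4407. The component was computed from these same arrays and parted the diets at week 20, so as a covariate it overlaps with diet there. A fall in the count can follow from this overlap whatever drives the component. The count of 793 thus cannot tell whether the component or the diet underlies the week 20 differences. At week 14, 81 features were called, 18 higher and 63 lower on high fat, from 1 male array per diet. Feature 31684 had an intensity of 137000 on the high-fat array and 419 on the chow array, and 218 to 500 on the other 14 arrays. Feature 31027 was at 210000 on the high-fat array, 1340 on the chow array and 957 to 1770 on the others. Feature 60591 was at 7900 on the chow array, 13.5 on the high-fat array and 14.1 to 33.3 on the others. Feature 10938 was at 878 on the chow array, 6.92 on the high-fat array and 13.7 to 117 on the others. Each feature called higher had its highest value of the 16 arrays on the high-fat array, and each called lower had it on the chow array. The spread came from the other 14 arrays alone, within their diet-by-week cells, so a call needs the week 14 arrays far apart against that spread. A large gap favours an extreme value on 1 of them, though it does not fix that this is the highest. These extremes are thus no separate support. They cannot tell an effect of diet from 1 odd array. With median centring the calls were 18 higher and 7 lower, and with no scaling 17 higher and 10 lower.

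The next comparison asked how expression moved with the weeks on each diet. Feature 36822 had a slope of 0.40 ± 0.0529 on the log2 scale per week on high fat (SE, 7 high-fat arrays), with an adjusted p of 0.0748. Its geometric mean intensity on high fat was 988 at week 4, 3645 at week 8, 41500 at week 14 and 82670 at week 20, against 492, 699, 1330 and 1672 on chow. It was higher on high fat in 7 of 7 pairs as labelled, and in 6 of 7 with the high-fat arrays of week 4 paired the other way. At week 4 the chow arrays were at 409 and 592 and the high-fat arrays at 400 and 2440. Feature 11806 had a slope of 0.23 ± 0.0326 (SE), with an adjusted p of 0.0748, and its geometric mean intensity on high fat was 564 at week 4 and 8967 at week 20, against 937 and 1713 on chow. Downward, feature 38496 had a slope of -0.10 ± 0.0234 and feature 62222 one of -0.69 ± 0.165 (log2 per week, SE). Each had an adjusted p of 0.887. Feature 62222 lay at the floor on 3 arrays, and on high fat it was at 5.33 at week 14 and at 3.85 and 8.27 at week 20. Its slope is therefore a rough value, and it was -0.27 with the week 0 chow arrays as the start of both diets. With the weeks given in the descriptions, the adjusted p was 0.945 for feature 36822 and 0.951 for feature 11806. With limma, 0 features passed for the slope on high fat, 0 for that on chow and 0 for their difference, and the counts at an unadjusted p under 0.05 were 2117, 931 and 1033. The first of these was 1055 without the array labelled female of high fat week 4 and 748 without both high-fat arrays of week 4. It was 7584 with no filter on dim features, where all 62976 features were tested. At an adjusted p under 0.1, 7 features had a slope on high fat, 7 of them upward. The difference of slopes was 0.25 ± 0.0668 for feature 36822 and 0.16 ± 0.0412 for feature 11806 (log2 per week, SE), each with an adjusted p of 1.00.

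The last comparison was between the sexes as labelled. With limma, 0 features passed for the sex difference, with 2936 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0828. The count of 2936 ran from 1787 with the first component as a covariate to 11047 with no filter. The latter is out of all 62976 features in place of 37785. Without both high-fat arrays of week 4 the count was 5111. The interaction of diet and sex gave 0, with 1576 at an unadjusted p under 0.05. The number of features that parted the 7 arrays labelled female from the 9 labelled male by 8-fold or more was 0. There were 9 features that parted the other 14 arrays this way while the arrays labelled female and male of high fat week 4 each lay with the other sex. Feature 38456 had intensities of 3180 to 7190 on the other 6 female arrays and 3.77 to 4.78 on the other 8 male arrays, but 7.46 on the array labelled female and 3170 on that labelled male. Feature 17614 was at 10700 to 22500 and 3.81 to 9.4, but at 33 and 10400 on those arrays. Feature 8524 was at 1890 to 3020 on the other male arrays and 3.52 to 9.88 on the other female arrays, but at 2270 on the array labelled female and 5.68 on that labelled male. Feature 41978 was at 1590 to 2500 and 3.93 to 9.87, but at 1770 and 5.21. With both arrays left out, 39 features were called, 5 higher in females and 34 higher in males.

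**Figure D4:**
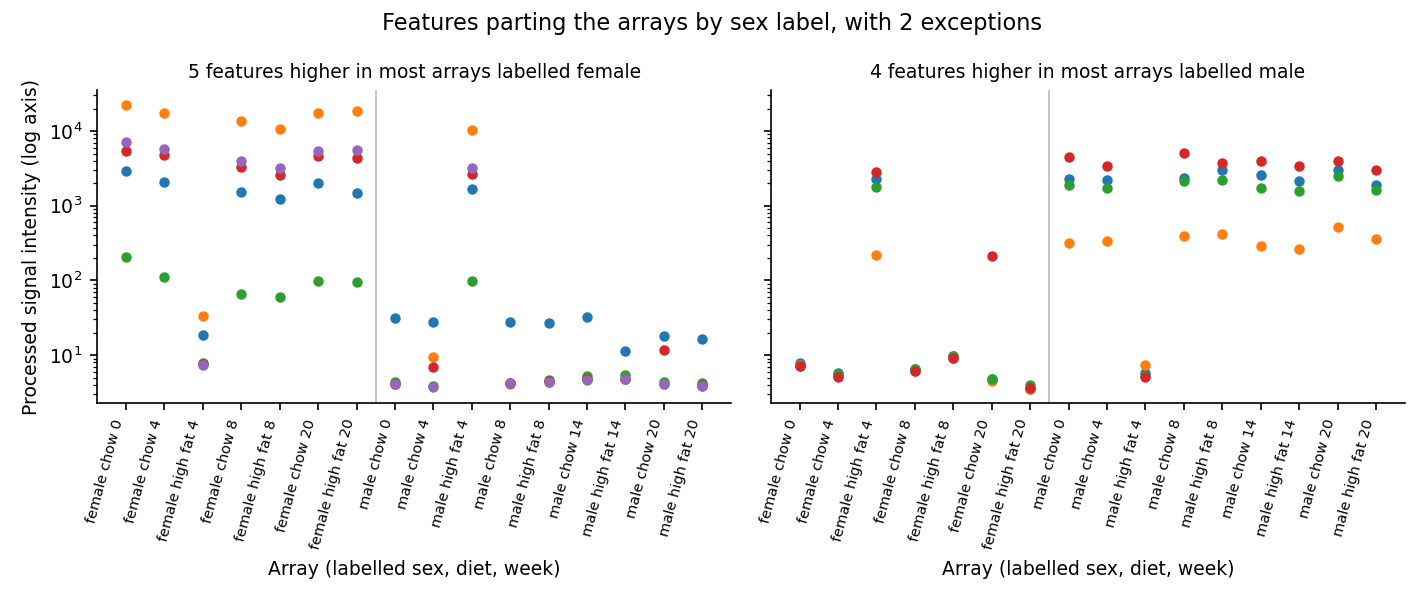
Intensity (y axis, log scale) of 9 features on the 16 arrays (x axis), 5 higher in most arrays labelled female (left) and 4 higher in most labelled male (right). Each colour is 1 feature within a panel and the grey line parts the labelled sexes; the arrays labelled female and male of high fat week 4 lie with the other sex.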

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

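The component covariate, common floor, no scaling, sex left out as a covariate, general settings at single weeks, week 4 arrays left out and other pairings were chosen after the data were seen. The cause was not tested for any change below. The diet effect called 1 feature with median centring and 1 with array weights, and 0 in the other 16 settings. Leaving out single arrays gave 0 to 2, with 2 without either week 14 array. As week is a covariate, leaving out either drops the week 14 pair from the diet estimate, so these are in effect 1 fit. At week 8 the count was 4 with no filter on dim features and 88 from the arrays of that week alone, which gave 476 at week 20. At week 14 it was 25 with median centring, 27 with no scaling, 252 with no filter, 30 without a trend, 479 with array weights and 24 with the component covariate, against 81. The slope on high fat called 1 feature with no scaling, 7 with a common floor, 1 with the component covariate, 6 with the week 0 chow arrays starting both diets, 2 with the weeks of the descriptions and 2 without the arrays of conflicting weeks. Leaving out single arrays gave 0 to 2, with 1 without the male chow array of week 0, 1 without the chow array of week 14 and 2 without the high-fat female array of week 20. The sex difference called 2 features without a trend, 31 with array weights, 10 in the chow arrays alone and 39 without both high-fat arrays of week 4. Leaving out single arrays gave 0 to 6, with 1 without either week 0 array, 6 without the array labelled female and 2 without that labelled male of high fat week 4. The slope on chow, the difference of slopes, the diet effect at week 4 and the interaction of diet and sex called 0 with limma in each setting run, with 278 to 7684, 450 to 3173, 803 to 3348 and 1003 to 4466 features at an unadjusted p under 0.05. Filters on dim features change how many features are tested, so such counts are not on 1 scale. The 8 named features of the diet effect and slope on high fat kept their direction in each setting run. Feature 20991 passed in 4 of 32 settings, with log2 differences of 1.09 to 1.44 and adjusted p of 0.00126 to 0.912. These 4 hold the fit without the week 14 pair once for each of its arrays. Feature 36822 passed in 3 of 30 (adjusted p 0.000275 to 1.00) and feature 11806 in 5 of 30 (0.00443 to 1.00). Without scaling, the median diet difference moved from -0.05 to -0.25 on the log2 scale. The block of pairs by sex and week called 0. The gene list tests, the tissue makeup covariates and the mean of all probes were not run. Features at the floor have no order.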

Other observations

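All explanations below were tested after the results had been seen, and the comparator for the variance on 1 component was made stricter after a first version.

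The 336 features high on the same 6 arrays lay no closer together in feature number than random sets. The median distance between successive numbers was 132, within the 116 to 144 of such sets. The numbers were not placed on rows and columns of the array, so a zone that cuts across the numbering stays open. After quantile normalization, 98.2% of them still parted the arrays in the same way. They were picked for gaps of over 4-fold, and the 75th percentiles of the arrays differed by less, from 462 to 809. This outcome was therefore largely fixed by the choice of features and is no separate test of scaling. Among the 6 arrays, 92.3% of their variance lay on 1 component, against 37.3% to 43.6% for other features of like variance. The set was picked for a shared pattern, and any jointly regulated set would vary together, so 1 kind of cell or tissue in varying amounts cannot be told apart from joint regulation. Whether the diet contributes cannot be told apart from chance with 7 pairs, as the exact p of the first component was 0.281. Without gene names neither the lesion nor tissue beside the aorta could be tested as a source.

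The 132 features high on 4 of these arrays were picked as low on the other 2, so their ratio to the first set was compared over the 4 arrays alone. The log2 ratio of the medians of the sets varied by 2.65 over the 4 arrays (95% bootstrap range 2.27 to 2.81). The bootstrap runs over features and no diet, sex and week had replicate arrays, so whether the sets share a source cannot be told apart from the spread between arrays. The range was 1.47 without the chow female array of week 4 (1.24 to 1.76) and 1.75 without the high-fat male array of week 14 (1.40 to 1.93). The ratio ran from -2.46 on the chow female array of week 4 to 0.19 on the high-fat male array of week 14. No biological explanation was tested for the second set.

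A candidate explanation for the sex-parted features is that the sex labels of the high-fat arrays of week 4 are exchanged. With these labels exchanged, 9 features parted the sexes by 8-fold or more, against 0 as labelled, 0 for each of the other 62 exchanges of 1 female and 1 male label and 0 in 100 random splits. Features picked on the other 14 arrays alone were the same 9, and on these the median signal of the lower of the 2 arrays was 0.294% of that of the higher (95% bootstrap range 0.235% to 3.37%), which argues against mixed RNA. Both arrays have the same diet and week, so an exchange of whole samples and one of labels alone stay open. The calls without both arrays, 39 features, included 8 of the 9. The 9 part the sexes on these same 14 arrays, so this overlap is no further support.

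Chance could not be excluded for any count at an unadjusted p under 0.05 that was tested against other splits. For the diet effect, 22 of 100 splits gave as many features as the real 2755, with a highest other count of 8340, and 14 of the 64 exchanges within pairs did, with a highest of 8034. For sex it was 17 of 100 against 2936, with a highest of 8014, and for the interaction of diet and sex 13 of 32 against 1576, with a highest of 6970. Both real counts rest on the sex labels as given, which are in doubt for the high-fat arrays of week 4. Without these arrays the counts were 5111 for sex and 3281 for the interaction, and these were not tested against other splits. For the slope on high fat it was 32 of 100 against 2117, with a highest of 4537. For the slope on chow it was 73 of 100 against 931, with a highest of 13329, and for the difference of slopes 67 of 100 against 1033, with a highest of 8300. The highest count of other splits was above the real count in each of these comparisons. The cause of such high counts was not tested.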
